A study of Rhizorhabdus wittichii RW1 with 15 samples.

How the data were processed

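The samples were 15 arrays of RNA from Sphingomonas wittichii RW1, 3 in each of 5 groups, which were taken from the sample titles. Per the file headers, each array was scanned in a single colour (Cy3) and read with Agilent Feature Extraction 10.7.1.1, which gives the intensity of each spot on a linear scale, not normalized between arrays. Per the labels' protocols, cDNA was labelled directly from random primers. Sand was sprayed with 10 ml of DBF solution (100 mg per ml) per 500 g, portions of 2 g were used at 10% moisture, and cells were re-extracted after 1 h. Control cells were added to sand only at the end, and extracted at once. The deposited flags of the scanner software (well above background, outlier, saturated) were used as given.

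A deposited table of log2 values of the same arrays holds 5335 gene names. In 100% of its rows the median over the arrays was 0, so that each gene had been centred. Its column medians were 0.014 for DBF-grown control 1, 0.04 for DBF-grown control 2 and 0 for each other array. Its columns correlated with centred scanner values at 0.87 to 0.98, with slopes of 0.85 to 0.97, so that the direction is the same. The scaling between arrays behind it is not given in the sources used here. It was used as an alternative, and 0 of its columns were left unmapped.

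Each array had 13416 spots, of which 12880 were not controls. These had 5342 names: 1066 with 1 spot, 1014 with 2 and 3262 with 3. Spots of a name are different probes, whose levels correlated at 0.17 to 0.22 across names. Of the names, 7 are reporters (GFP, LuxAB, echerry) and were left out of the fits, and 19 stand for several numbered tags. The log2 processed signal minus the 75th percentile of the array was averaged over the probes of a name. A gene was tested when at least 1 probe was well above background on all 3 arrays of at least 1 group, which left 5306. No spot was marked as saturated (0 on all arrays). No pair of arrays held equal values (0% of spots), so each array was counted as 1 replicate. Arrays correlated at 0.96 to 0.99 within groups and at 0.78 to 0.95 between groups.

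Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of all 15 arrays. The groups then share an estimate of the spread, although they did not vary alike. The SDs of Swit_4895, Swit_4896, Swit_4897 and Swit_4902 were 0.44 to 0.67 in the DBF-grown controls. In salicylate-grown cells in sand with DBF they were 0.04 to 0.07. Fits of only the groups compared gave 1250 instead of 2477 genes for the DBF-grown response to sand with DBF. For clean sand they gave 2884 instead of 2447, and between the sands 2181 instead of 1617. P-values were adjusted with the Benjamini-Hochberg method within each of 7 comparisons, with a threshold of 0.05. Counts at a log2 difference of at least 1 (2-fold) are also given. An exact permutation test of 3 against 3 arrays cannot go below 0.1, two-sided. In simulated arrays with the spread of these genes and 200 changed genes among 5306, the DBF-grown response to sand with DBF had 85.1% of 2-fold and 56.7% of 1.5-fold changes recovered, with 4.17% of the calls false. For the difference between the responses of the precultures, 61.2% of 2-fold and 17.9% of 1.5-fold changes were recovered, with 6.35% of the calls false. The false share was 5.19% for clean sand, 8.33% for salicylate-grown cells in sand with DBF, 4.61% between the sands, 5.59% between the liquid controls and 7.55% between precultures in sand, so that it exceeded 5% in 5 of the 7 comparisons. Each comparison was simulated in a single draw, so that these shares do not rank the comparisons. The simulated noise was independent between arrays, had a single spread per gene for all groups and held no slide effect. Between 1590 and 3902 genes passed in the comparisons of the data. Recovery and false shares depend on how many genes change, so that those simulated with 200 need not hold for these lists. In the data the consensus correlation within a slide was 0.51, and the shares do not cover errors from slide.

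The rule for named genes took the 10 largest increases and decreases (5 for the difference of responses) among genes past the threshold whose arrays did not overlap between groups and that were well above background in the higher group, plus 4 tags. The rule also asked for an informative product. That part could not be applied: the reference table used here describes another strain (assembly ASM1760742v1), and 0 of the array's tags were found among its 5867 genes. For the same reason, tests of 37 gene lists planned by product were not run, and no gene is named. At most 2 tags per direction are printed. The 4 tags had been chosen from prior knowledge of the strain as bearing on the breakdown of DBF, which could not be checked against a table here.

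After the data were examined, 3 analyses by tag number were added: the correlation of neighbouring tags against 1000 permutations, runs of at least 4 consecutive tags that passed and lay at least 2-fold from the median of all genes, and stretches of at least 8 such tags merged over the comparisons, which gave 5. Tag numbers are those of the array and no genome position is given. Blocks of 100 tag numbers were tested with camera.

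Slide and scan coincide. Slide was tested as a fixed block, as a random block (duplicateCorrelation) and within slides. On slide 2 the lone DBF-grown control was assumed to vary like the other groups. The fixed block rests on DBF-grown controls 1 and 2 against control 3. Controls 1 and 2 had 336 and 106 spots marked as outliers, against at most 31 on any other array. Values with slide as a block may therefore also carry differences particular to these arrays. Replicate numbers come from the titles, which do not say that a number marks a shared culture or day. Whether they pair arrays was checked from the correlation across genes of the deviations from the group means. All 3 same-numbered pairs exceeded 0.1 in 2 of the 6 compared pairs of groups: between the liquid controls (0.198 to 0.422) and between precultures in sand with DBF (0.139 to 0.212). In each of these, 6 of 6 arrays correlated best with their own number, and the numbers were taken as pairing the arrays there, on the basis of these correlations. Deviations of 3 arrays from their own mean depend on each other, so that the 6 arrays are not separate checks and the pairing is not certain. The other alternatives were quantile normalization, median scaling, normexp with an offset of 50, the filter on dim genes, the summary of probes, the arrays in the fit, an intensity trend, the replicate number as a block (for the paired groups also in a fit of those groups alone or of the paired differences), the deposited log2 table, spots marked as outliers, undetected arrays at the lowest signal well above background (for 2 printed tags) and each array left out in turn. The planned normexp on the mean signal was not run, since the arrays' columns used here give the median signal, which took its place.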

Results

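Transcript levels were measured on 15 one-colour arrays of the dibenzofuran-degrading bacterium Sphingomonas wittichii strain RW1, in 5 groups of 3 arrays. Cells were grown in liquid medium with salicylate (5 mM) or with crystals of the aromatic compound dibenzofuran, DBF (1.6 g per litre), as the only carbon source. They were then kept for 1 h either in suspension (the liquid controls), in moist sand sprayed with DBF, or in moist sand without it. Clean sand was used here for salicylate-grown cells only. The median processed signal of an array lay between 125.7 and 646.5, and between 89.2% and 99.2% of the spots were well above background. The number of arrays per group limits the precision. The labels do not say that arrays of a group came from separate cultures, so that the p-values measure the spread between these arrays, which may be technical.

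Levels are log2 signals relative to the 75th percentile of the same array. Of 5335 gene names on the array, 5306 were tested. Genes are given as locus tags, since the files do not pair tags with names or products. At most 2 tags that rose and 2 that fell are printed for each comparison, beside 4 tags (Swit_4895, Swit_4896, Swit_4897 and Swit_4902) chosen before the data were examined. Stretches of consecutive tag numbers were chosen after their values were seen. Every tag of a run had passed in the same direction in the comparison that gave the run, so that full counts there follow from the choice. This holds for 794 to 801 in clean sand, 5375 to 5382 in the liquid controls and 3939 to 3947 between precultures in sand. It also holds for 1332 to 1358 in the difference of responses. In other comparisons runs covered parts of a stretch. Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

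The arrays lay on 2 slides, each scanned separately. Slide 1 held DBF-grown controls 1 and 2, the 3 salicylate-grown controls and the 3 clean sand arrays. Slide 2 held DBF-grown control 3 and all arrays of sand with DBF. The titles of the 3 DBF-grown arrays in sand with DBF are the only ones that carry a note on hot-phenol RNA extraction, while the extraction text is the same for all samples. Whether the other groups were extracted in another way was not settled, and it bears on each comparison with that group.

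**Figure D1:**
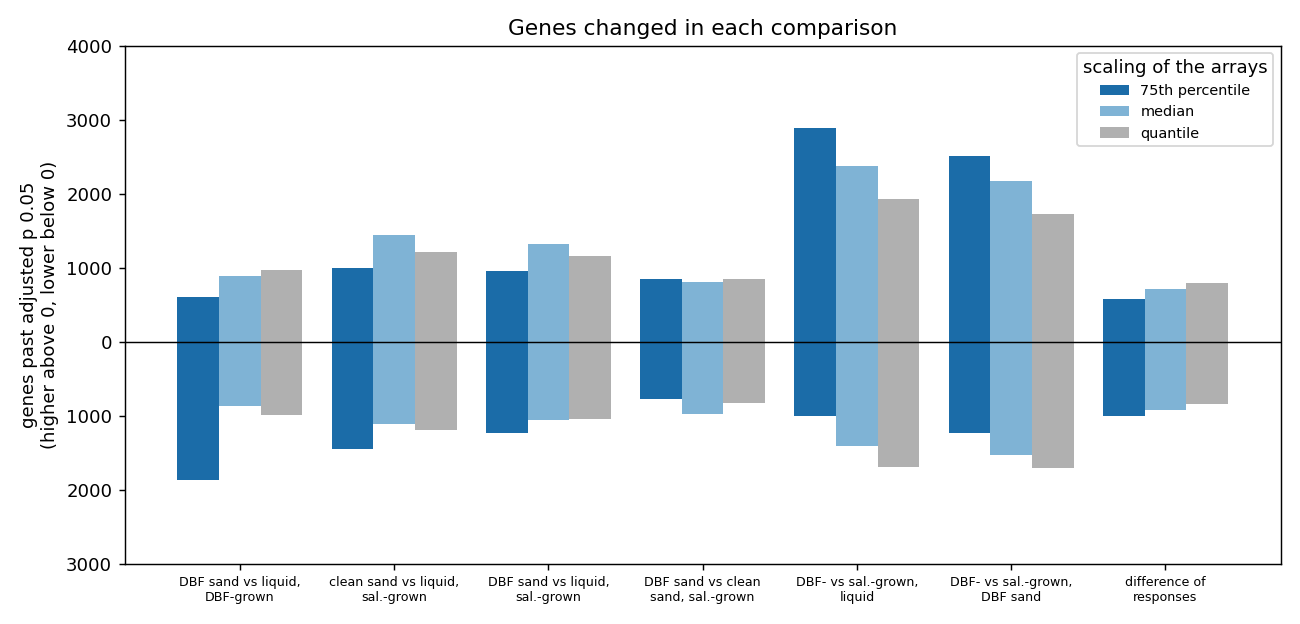
Genes past the threshold in each of the 7 comparisons (vertical axis, number of genes, higher above 0 and lower below 0) under 3 scalings of the arrays. In the DBF-grown response to sand with DBF, 612 genes were higher and 1865 lower with the 75th percentile, against 884 and 873 with median scaling.

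How DBF-grown cells responded to 1 h in sand with DBF was asked first. Consecutively numbered tags from 1332 to 1358 moved together. All 27 measured members (26 with slide as a block) were higher in sand than in the liquid control, with a median log2 difference of 3.27 (range 0.54 to 4.36). The mean level of the stretch was -1.42 ± 0.20 (SD, n = 3) in the control and 1.68 ± 0.17 in sand. Of 15 tags numbered 2983 to 2997, 14 were higher and 1 did not pass, with a median log2 difference of 1.43, and 8 were higher with normexp background correction. Swit_0862 rose from 0.95 ± 0.84 to 5.90 ± 0.25 (SD, n = 3), a 30.9-fold difference (log2 difference 4.95 ± 0.28 SE, adjusted p = 2.03e-09). Swit_3810 rose 21.0-fold (adjusted p = 5.27e-10). Swit_3730 was 24.1-fold lower in sand (log2 difference -4.59 ± 0.22 SE, adjusted p = 7.83e-10), and Swit_3144 was 19.2-fold lower. Of the 4 tags chosen beforehand, Swit_4896 and Swit_4897 fell by 1.93 and 2.45 on the log2 scale (adjusted p = 1.08e-05 and 3.15e-07). Swit_4895 had a log2 difference of -1.27 (adjusted p = 0.00156) and Swit_4902 one of -0.61 (adjusted p = 0.0161). Over the alternatives, the adjusted p of Swit_4895 lay between 0.000129 and 0.131 and that of Swit_4902 between 0.00152 and 0.497, the highest in both with slide as a block (log2 differences -0.63 and -0.20). Swit_4902 also lost the call without DBF-grown control 1 (-0.37, adjusted p = 0.0687) and without array 3 of sand with DBF (-0.50, adjusted p = 0.0688).

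In the same comparison 2477 genes differed, 612 higher and 1865 lower in sand with DBF. The median difference of all genes was -0.33, and relative to it 395 genes were at least 2-fold higher and 138 at least 2-fold lower. Median scaling gave 884 higher and 873 lower, and quantile normalization 977 and 984. A fit with slide as a block gave 1614 genes, 751 higher and 863 lower. Within slide 2, where a single control array stood against 3 sand arrays, 1453 differed, 648 higher and 805 lower. Of the 2477 genes, 1224 remained in the same direction with the block. Normexp gave 1619, 359 higher and 1260 lower, and a fit of only the groups compared gave 1250, 410 higher and 840 lower. Without DBF-grown control 2 the count was 1699 (659 higher and 1040 lower), and without array 2 of sand with DBF it was 1693 (540 higher and 1153 lower).

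**Figure D2:**
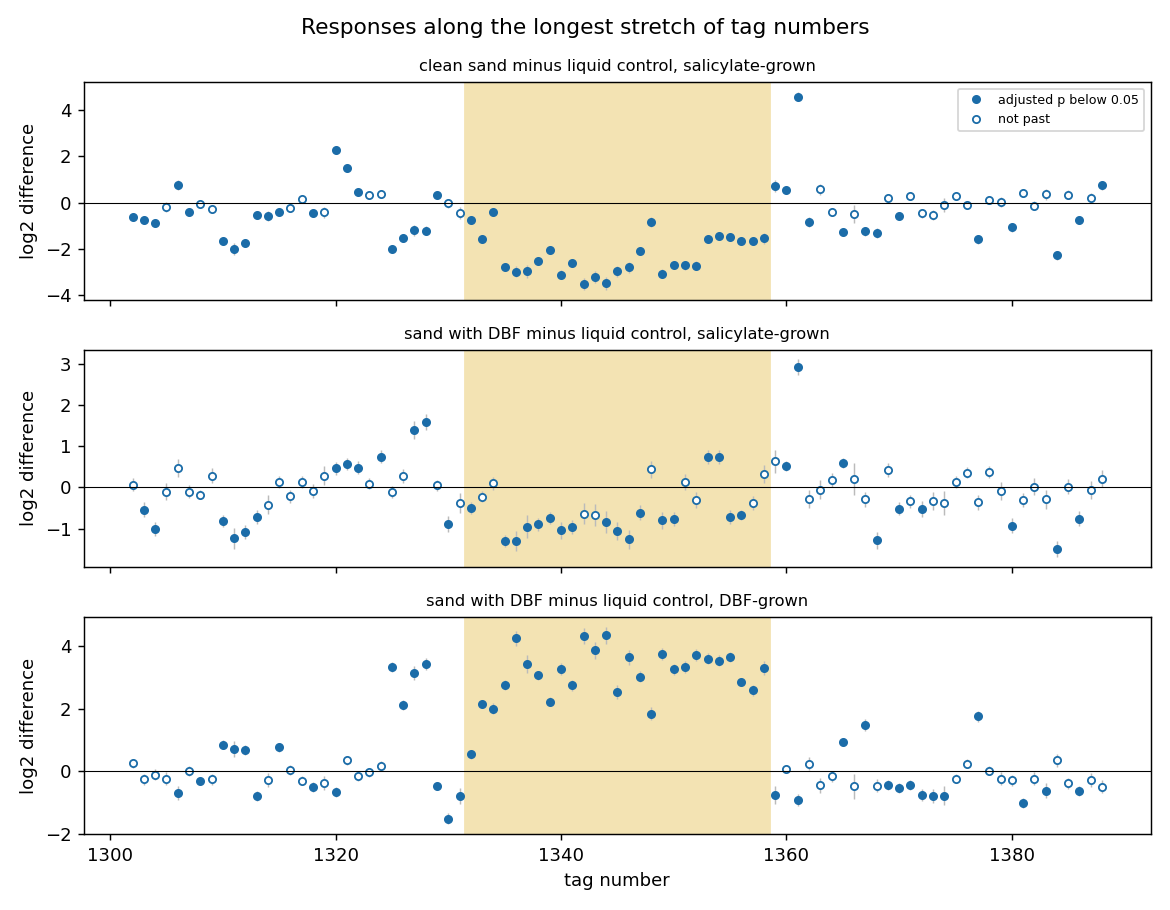
log2 differences (vertical axes, bars are SE, 3 arrays per group) of single tags along the tag number (horizontal axis) around the shaded stretch from 1332 to 1358, in 3 comparisons with the liquid controls. All 27 tags of the stretch (26 with quantile normalization, median scaling or normexp) were lower in clean sand with salicylate-grown cells, and all 27 (26 with slide as a block) were higher in sand with DBF with DBF-grown cells.

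Salicylate-grown cells in clean sand addressed the response to sand without the compound. The stretch from 1332 to 1358 went the other way here: all 27 members (26 with quantile normalization, median scaling or normexp) were lower in sand, with a median log2 difference of -2.63, and its mean level was 0.19 ± 0.15 (SD, n = 3) in the control and -2.09 ± 0.01 in clean sand. All 15 tags from 2983 to 2997 (11 with normexp) were also lower, with a median log2 difference of -1.43. All 8 tags from 794 to 801 were higher, with a median log2 difference of 3.43 (range 1.05 to 5.73). Swit_2334 rose from -1.61 ± 0.70 to 4.90 ± 0.06 (SD, n = 3), a 91.2-fold difference (log2 difference 6.51 ± 0.31 SE, adjusted p = 1.31e-10), and Swit_3927 rose 89.2-fold (adjusted p = 1.08e-09). Both tags have a single probe. Swit_1200 was 29.7-fold lower (adjusted p = 2.9e-11, also a single probe) and Swit_0975 was 26.0-fold lower (adjusted p = 1.17e-11). The 4 tags chosen beforehand were higher in clean sand, by log2 differences of 1.20 (Swit_4895, adjusted p = 0.00157), 1.86 (Swit_4896, adjusted p = 8.98e-06), 1.42 (Swit_4897, adjusted p = 6.37e-05) and 1.88 (Swit_4902, adjusted p = 5.49e-07). That of Swit_4895 was 0.66 with quantile normalization (adjusted p = 0.08, the highest of the alternatives, from 0.000245).

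In clean sand 2447 genes differed, 996 higher and 1451 lower. The median difference of all genes was -0.11, and relative to it 438 genes were at least 2-fold higher and 425 at least 2-fold lower. Median scaling gave 1444 higher and 1111 lower, while normexp gave 1274 genes, 590 higher and 684 lower. All 6 arrays lay on slide 1, and slide as a block in the fit of all groups gave 2731 genes, 1138 higher and 1593 lower.

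**Figure D3:**
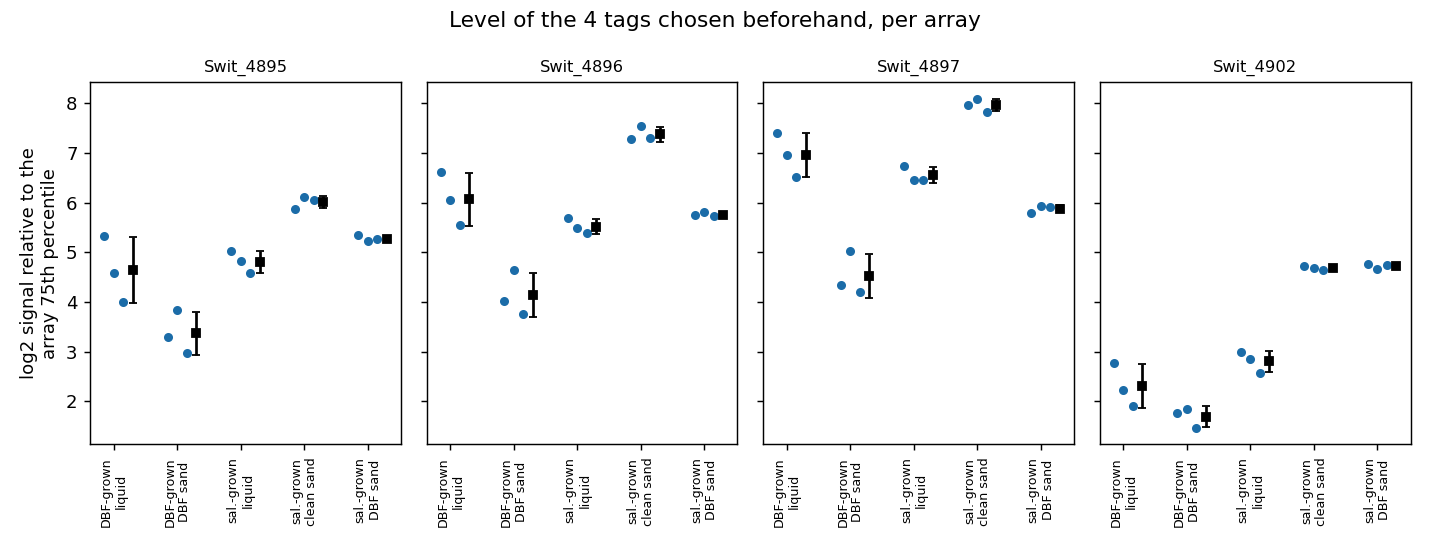
Level of the 4 tags chosen beforehand (vertical axis, log2 signal relative to the 75th percentile of the array) in the 5 groups. Points are arrays, and squares with bars are the mean and SD of 3 arrays. Swit_4897 stood at 7.97 in clean sand and 4.52 in DBF-grown cells in sand with DBF.

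Salicylate-grown cells were also placed in sand with DBF. Against their liquid control, Swit_4922 rose from -0.69 ± 0.10 to 4.56 ± 0.14 (SD, n = 3), a 38.0-fold difference (log2 difference 5.25 ± 0.22 SE, adjusted p = 5.34e-11). Swit_0798 rose 37.4-fold (adjusted p = 3.49e-10). It lies among the 8 tags from 794 to 801, all of which (7 with normexp) were higher, with a median log2 difference of 3.14. Swit_1200 and Swit_0975 were again lower, 29.3-fold and 24.9-fold (adjusted p = 5.34e-11 and 1.42e-11). In the stretch from 1332 to 1358, 16 tags were lower, 2 were higher and 9 did not pass, with a median log2 difference of -0.66. When slide was a block, 3 were lower, 1 was higher and 23 did not pass. Swit_4902 was higher by 1.92 (adjusted p = 5.27e-07), whereas Swit_4895 and Swit_4896 differed by 0.46 and 0.24 (adjusted p = 0.178 and 0.436). Swit_4897 had a log2 difference of -0.67 (adjusted p = 0.0222), which was -0.01 with slide as a block (adjusted p = 0.99, the highest of the alternatives, from 0.00144). It also lost the call without salicylate-grown control 1 (adjusted p = 0.0821) or without array 1 of sand with DBF (adjusted p = 0.0689). With that block Swit_4895 and Swit_4896 differed by 1.42 (adjusted p = 0.0117) and 1.03 (adjusted p = 0.0365), the lowest p of their alternatives, which reached 0.762 and 0.981.

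In this comparison 2191 genes differed, 962 higher and 1229 lower. The median difference was -0.10, and relative to it 404 genes were at least 2-fold higher and 349 at least 2-fold lower. Median scaling gave 1316 higher and 1055 lower, and normexp 547 and 1403. The groups lay on different slides, so that no value within a slide could be had. With slide as a block, estimated through the DBF-grown controls, 1880 genes differed, 1216 higher and 664 lower. Of the 2191 genes, 1285 remained in the same direction.

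The effect of DBF in sand, as against sand alone, was addressed in salicylate-grown cells. Swit_4923 rose from -0.90 ± 0.20 to 4.35 ± 0.11 (SD, n = 3), a 37.9-fold difference (log2 difference 5.25 ± 0.18 SE, adjusted p = 1.96e-11, single probe), and Swit_4925 rose 36.2-fold (adjusted p = 4.92e-12). Swit_4367 was 38.6-fold lower (adjusted p = 3.34e-09), with 2 of 3 arrays of sand with DBF above background (32.2-fold with the other at the lowest signal well above background), and Swit_4363 was 38.0-fold lower (adjusted p = 4.09e-11), its 3 probes differing between -7.87 and -2.03. In the stretch from 1332 to 1358, 26 of 27 tags were higher in sand with DBF than in clean sand, with a median log2 difference of 1.70. With slide as a block 25 passed, and with normexp 22 (median log2 difference 1.32). Of the tags from 2983 to 2997, 13 of 15 were higher (8 with normexp). Swit_4897 was lower, with a log2 difference of -2.09 (adjusted p = 2.6e-06), and Swit_4902 differed by 0.04 (adjusted p = 0.901). Swit_4896 had a log2 difference of -1.62 (adjusted p = 7.27e-05), which was -0.83 with slide as a block (adjusted p = 0.109, the highest of the alternatives, from 1.63e-05). That of Swit_4895, -0.74 (adjusted p = 0.0457), was 0.22 with slide as a block (adjusted p = 0.729). Its adjusted p lay between 0.000637 and 0.758 over the alternatives, and leaving out any of the 6 arrays ended the call (adjusted p from 0.0665 without clean sand array 1 to 0.121 without clean sand array 2).

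Between sand with DBF and clean sand 1617 genes differed, 845 higher and 772 lower, with 496 of them at least 2-fold. The balance depended on the processing: median scaling gave 814 higher and 976 lower, and normexp 347 and 565 (912 in all). The groups again lay on different slides. Slide as a fixed block gave 1266 genes, 965 higher and 301 lower, and as a random block 1036 differed, 711 higher and 325 lower. Of the 1617 genes, 803 remained in the same direction with the fixed block.

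Growth substrate was compared in the liquid controls. Swit_5364 stood at 4.11 ± 0.58 (SD, n = 3) in DBF-grown cells and at -3.41 ± 0.09 in salicylate-grown cells, a 184-fold difference (log2 difference 7.52 ± 0.21 SE, adjusted p = 7.91e-13). Swit_5365, with the next tag number, was 36.9-fold higher (adjusted p = 3.53e-08). Both have a single probe. All 8 tags from 5375 to 5382 were higher in DBF-grown cells, with a median log2 difference of 2.54 (1.40 with normexp). Swit_3376 was 59.7-fold lower in DBF-grown cells (adjusted p = 7.91e-13) and Swit_0619 was 50.7-fold lower (adjusted p = 3.24e-11). In the stretch from 1332 to 1358, 26 of 27 tags (23 with normexp) were lower in DBF-grown cells, with a median log2 difference of -1.55. Differences of the tags chosen beforehand were -0.17 for Swit_4895 (adjusted p = 0.564), 0.55 for Swit_4896 (adjusted p = 0.0462), 0.41 for Swit_4897 (adjusted p = 0.0968) and -0.51 for Swit_4902 (adjusted p = 0.0232). Relative to the median difference of all genes (0.50) these values were -0.675, 0.049, -0.088 and -1.008. That median depended on level, and was 0.173 in the highest of 4 classes of genes by mean level and 0.972 in the lowest. Swit_4896 lies in the highest class, so that its value relative to all genes does not remove the shift at its level. Over the alternatives the adjusted p lay between 0.00177 and 0.26 for Swit_4896, between 0.000116 and 0.487 for Swit_4897 and between 0.000516 and 0.156 for Swit_4902. Within slide 1, Swit_4896 differed by 0.81 (adjusted p = 0.00335), Swit_4897 by 0.64 (adjusted p = 0.00705) and Swit_4902 by -0.30 (adjusted p = 0.156). Without DBF-grown control 1, Swit_4896 differed by 0.28 (adjusted p = 0.26), and without DBF-grown control 3, Swit_4897 differed by 0.64 (adjusted p = 0.0145) and Swit_4902 by -0.30 (adjusted p = 0.121). The call of Swit_4896 was also lost without DBF-grown control 2 or salicylate-grown control 2 or 3, and that of Swit_4902 without DBF-grown control 2 or salicylate-grown control 1 or 2.

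Between the liquid controls 3902 genes differed, 2896 higher and 1006 lower in DBF-grown cells. The median difference of all genes was 0.50, and relative to it 661 genes were at least 2-fold higher and 833 at least 2-fold lower. Median scaling gave 2372 higher and 1413 lower, and quantile normalization 1932 and 1686. Within slide 1, with 2 DBF-grown controls, 3924 genes differed, 3045 higher and 879 lower. Slide as a block gave 3958, 3078 higher and 880 lower.

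The same question was put after 1 h in sand with DBF. Swit_5364 was 65.5-fold higher in DBF-grown cells (log2 difference 6.03 ± 0.21 SE, adjusted p = 4.47e-11) and Swit_5365 was 22.0-fold higher (adjusted p = 3.15e-07). All 8 tags from 5375 to 5382 were higher, with a median log2 difference of 2.22 (1.51 with normexp and 1.55 with quantile normalization). All 27 tags from 1332 to 1358 (26 with median scaling) were higher in DBF-grown cells, with a median log2 difference of 2.18. All 9 tags from 3939 to 3947 were lower, with a median log2 difference of -0.85. Swit_3162 was 12.1-fold lower (adjusted p = 6.8e-08) and Swit_2810 was 11.8-fold lower (adjusted p = 1.06e-08). The 4 tags chosen beforehand were lower in DBF-grown cells, with log2 differences of -1.91 (Swit_4895, adjusted p = 1.84e-05), -1.62 (Swit_4896, adjusted p = 2.7e-05), -1.36 (Swit_4897, adjusted p = 6.09e-05) and -3.04 (Swit_4902, adjusted p = 2.43e-08).

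In sand with DBF 3739 genes differed between precultures, 2507 higher and 1232 lower in DBF-grown cells. The median difference was 0.33, and relative to it 621 genes were at least 2-fold higher and 809 at least 2-fold lower. Median scaling gave 2173 higher and 1526 lower, and quantile normalization 1723 and 1702. All 6 arrays lay on slide 2, and slide as a block in the fit of all groups gave 3954 genes, 2630 higher and 1324 lower.

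The response to sand with DBF was then compared between precultures, as the DBF-grown minus the salicylate-grown log2 difference. All 27 tags from 1332 to 1358 had a more positive response in DBF-grown cells, by a median of 3.71, as did all 15 tags from 2983 to 2997 (9 with normexp), by a median of 1.66. Swit_1336 lies in the longer stretch and differed by 5.56 ± 0.35 SE (adjusted p = 1.42e-08, single probe). Swit_0619 rose from -1.50 to 1.73 in DBF-grown cells and stood at 4.16 in the control and 2.02 in sand with salicylate-grown cells, a difference of responses of 5.37 (adjusted p = 8.45e-09). Swit_0798 had a response more negative by -5.08 (adjusted p = 4.39e-08) and Swit_2324 had a value of -4.70 (adjusted p = 1.36e-08), which is not exact. Its 1 probe was well above background on 1 of 3 salicylate-grown control arrays (mean level -6.37). With the other 2 at the lowest signal well above background on the same array, a setting chosen after the data were seen, the difference was -3.43 (adjusted p = 1.89e-05), and with normexp it was -2.16 (adjusted p = 0.0102, the highest of the alternatives, from 1.42e-09). Of the 8 tags from 794 to 801, 7 had a more negative response and 1 did not pass. These tags did not fall in DBF-grown cells: 4 were higher in sand (2 with normexp, 6 with slide as a block) and 0 lower, with a median log2 difference of 0.41. Their mean level was 0.74 in the DBF-grown and -1.14 in the salicylate-grown liquid controls. In sand with DBF it was 1.25 and 1.97. In all, 1590 genes differed in response, 582 more positive and 1008 more negative. Against a median difference of -0.21, 470 genes were at least 2-fold more positive and 317 at least 2-fold more negative. Quantile normalization gave 795 more positive and 839 more negative. With normexp 752 genes differed, 344 more positive and 408 more negative, and 47.3% of the 1590 calls were kept. Slide as a block gave 2028 genes, 580 more positive and 1448 more negative.

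The responses were set side by side across the 5306 genes, which are not independent replicates. The DBF-grown response to sand with DBF had a Pearson correlation of -0.10 with the salicylate-grown response to clean sand (Spearman 0.02), which shares no arrays with it, and -0.03 on slide 2 alone. Genes that were higher in DBF-grown cells and lower in clean sand numbered 311, where independent lists would share 167.4, while 312 were lower in DBF-grown cells and higher in clean sand, against 350.1. In both, 127 were higher and 518 lower, against 114.9 and 510.0. With median scaling these counts were 334 (185.1), 234 (237.6), 263 (240.6) and 201 (182.8), with the values for independent lists in brackets. With the salicylate-grown response to sand with DBF it had 0.37 (0.36 on slide 2 alone), and 250 genes were higher and 723 lower in both, where independent lists would share 111.0 and 432.0. Median scaling gave 434 (219.3) and 422 (173.6). Its correlation with the difference between sand with DBF and clean sand in salicylate-grown cells was 0.61 (0.51 on slide 2 alone, with its single control), with 382 genes higher and 515 lower in both, against 97.5 and 271.3 for independent lists. Median scaling gave 459 (135.6) and 424 (160.6). The responses of salicylate-grown cells to clean sand and to sand with DBF correlated at 0.73. They share the liquid controls, and unchanged groups simulated against the same controls gave 0.50. The observed covariance was 0.58 and the simulated one 0.02, a difference of 0.555. In both of these comparisons 593 genes were higher and 825 lower, against 180.6 and 336.1 for independent lists. Median scaling gave 900 (358.1) and 637 (220.9). Simulated unchanged groups shared 0 calls, and part of the excess may come from the shared controls.

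**Figure D4:**
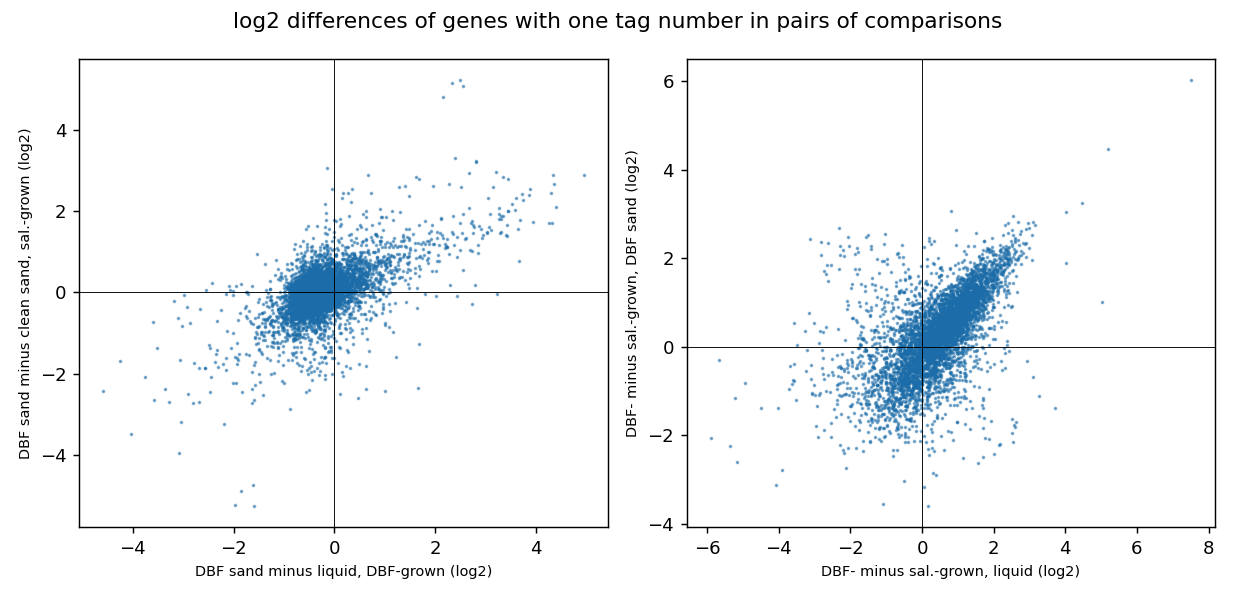
log2 differences of genes with a single tag number in pairs of comparisons that share no arrays. On the left, sand with DBF minus liquid control in DBF-grown cells (horizontal) is set against sand with DBF minus clean sand in salicylate-grown cells (vertical), with a correlation of 0.61 over all 5306 genes. On the right, the difference between precultures in the liquid controls (horizontal) is set against that in sand with DBF (vertical), with a correlation of 0.59.

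The differences between precultures in the liquid controls and in sand with DBF correlated at 0.59 over different arrays, and at 0.56 with both within a slide. Of the 3902 genes that differed in the controls, 2635 (67.5%) differed in the same direction in sand, and 346 in the opposite direction. Independent lists would share 1368 higher and 233.6 lower genes, where 2044 and 591 were shared. With median scaling 1674 and 910 were shared, against 971.4 and 406.4.

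Tags with neighbouring numbers moved together in every comparison. Over 5193 pairs of consecutive tag numbers, the correlation of the log2 differences lay between 0.39 and 0.52 in the 7 comparisons. The highest value in 1000 permutations of the tags was 0.06, giving p = 0.001 in each comparison, the smallest they can give. In the DBF-grown response to sand with DBF, 92 tags lay in 15 runs of at least 4 consecutive tags that were at least 2-fold above the median of all genes. Permuted tags gave at most 9.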

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

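The test of array brightness, the sorting of splits by the pairs they part or keep, the resemblance of the DBF-grown response to the difference between the sands, with its value on slide 2 alone, and the correlation of the slide difference with the DBF-grown response were chosen after results had been seen.

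A difference between groups was found for 1590 genes, whose response to sand with DBF differed between precultures by the test of that difference. In 112 of these the DBF-grown response was a rise and the salicylate-grown one a fall, each past the threshold, and in 111 the reverse. Independent lists would share 141.8 and 338.1, so that opposite calls were fewer than for such lists. Lists with median scaling shared 115 (175.8) and 78 (216.5), with the values for independent lists in brackets. The numbers were taken as pairing the precultures in the controls and in sand, from correlations that exceeded 0.1 in 2 of 10 pairs of groups. In no pair of groups of the same preculture did all 3 same-numbered pairs exceed 0.1, so that the pairing is not certain. If it holds, 10 splits keep same-numbered arrays together, which are too few for a share under 0.05. Of these the real split alone (1 of 10) gave as many genes, with a highest other count of 0. Of 100 splits drawn within each preculture without regard to the numbers, 2 gave as many, the real one included, and the highest other gave 2882 genes. It exchanges sand and control in salicylate-grown cells alone, and so measures the sum of the responses, which points to the structure of the samples.

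The same test picked out the 4 tags chosen beforehand, with differences of -1.74 (Swit_4895), -2.17 (Swit_4896), -1.78 (Swit_4897) and -2.53 (Swit_4902). Signals in some reporter probes outside the comparisons were above the negative control spots of the same arrays. The mean log2 excess over 15 arrays was 7.04 for LuxAB_2, 6.61 for LuxAB_3 and 4.43 for GFP_3, each well above background on 15 arrays. It was 0.93 for echerry_1, which was well above background on 2 arrays. The excess was 0.01 for LuxAB_1, 0.89 for GFP_1 and 0.31 for GFP_2, each well above background on 0 arrays. Probes of the same reporter thus disagreed, and the source of the signals was not tested.

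For the other comparisons, 6 arrays allow 10 splits, which are too few for a share under 0.05. The real split alone (1 of 10) gave as many genes in each. The real and highest other counts were 2477 and 4 for DBF-grown cells in sand with DBF, 2447 and 0 for clean sand, 2191 and 0 for salicylate-grown cells in sand with DBF, 1617 and 0 between the sands, 3902 and 0 between the liquid controls, and 3739 and 0 between precultures in sand. In these last 2, where numbers were taken as pairing the arrays, 4 of the 10 splits part all 3 pairs, the real one included, and 6 part 1 pair. The highest count was 0 in both kinds, the real split aside.

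More genes were higher than lower in the DBF-grown liquid controls. A single scale factor for each array is argued against, since, of 4 equal classes of genes by mean level, the lowest had a median difference that exceeded that of the highest by 0.80 (95% bootstrap interval over genes 0.72 to 0.89). The mean log2 75th percentiles of the DBF-grown and salicylate-grown controls differed by -0.005. That mean includes DBF-grown control 3, on slide 2, at 10.19. On slide 1 the values were 8.654 and 9.166 in the DBF-grown controls. In the salicylate-grown controls they were 8.788, 10.35 and 8.888. Since the near-equal means rest on an array of the other slide, the test cannot judge array brightness. A signal added to all of the strain's own probes stays open: 4.6% of the genes of the lowest class were lower, between the bounds of 1% and 5% set beforehand. A biological difference between precultures, which the design names, stays open and was not tested separately.

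The DBF-grown response to sand with DBF resembled the difference between the sands in salicylate-grown cells. On slide 2 alone the correlation was 0.505 (interval over genes 0.475 to 0.534). The bound of 0.3 set beforehand was passed, but that bound did not allow for the design, in which slide 2 holds 1 DBF-grown control. The slide difference of the DBF-grown controls correlated with the salicylate-grown difference at 0.14 (interval 0.116 to 0.166) but with the DBF-grown response at -0.016, which goes against slide as the source, again through that array. Since each of these values rests on 1 control, slide and a shared response to DBF cannot be told apart for this pattern.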

How the results depend on the processing

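Normexp on the median signal, the mean over detected probes only, the within-slide fits, the paired fits of 2 groups alone and of paired differences, undetected arrays at the lowest signal well above background, the 2 added correlations, and the tests by tag number were chosen after seeing the data. The planned normexp on the mean signal and the planned gene list tests with their alternatives were not run. Normexp on the median signal gave 1619 genes for DBF-grown cells in sand with DBF, 1274 for clean sand, 912 between the sands and 752 for the difference of responses. For DBF-grown cells in sand with DBF, slide as a fixed block gave 1614, only the groups compared 1250 and slide 2 alone 1453. Between the sands, slide as a random block gave 1036. Other counts stayed within 1.5 times. With the replicate block the counts were 2364, 2414, 2149, 1558, 3880, 3698 and 1544 in the order of the report. Where the numbers were taken as pairing the arrays, a fit of the 2 groups alone with that block gave 3696 genes between the liquid controls and 3950 between precultures in sand. A fit of the differences of same-numbered arrays gave 1553 for the difference of responses, and no such block changed a call of a printed tag. In the other 4 compared pairs of groups same-numbered arrays correlated at -0.384 to 0.275 and the numbers were not taken as pairing. Leaving out an array gave 1693 to 2878, 2037 to 2214, 1803 to 1968, 1237 to 1347, 3550 to 3958, 3315 to 3656 and 1282 to 2028 genes. Correlations of the DBF-grown response were -0.12 (quantile), -0.062 (normexp), -0.032 (slide 2 alone) and -0.13 to -0.065 (arrays left out, -0.065 without DBF-grown control 1) with clean sand, 0.34, 0.47 and 0.34 to 0.38 with the salicylate-grown response to sand with DBF, and 0.69 (normexp), 0.505 (slide 2 alone) and 0.57 to 0.63 with the difference between the sands. Those of the salicylate-grown responses were 0.74, 0.70 and 0.72 to 0.74, and those between precultures 0.55, 0.56, 0.559 (within slides) and 0.56 to 0.61. Of 1208 alternative values of 56 tag differences, 1149 kept direction and side of the threshold, 47 lost and 11 gained the call, all in the 4 tags chosen beforehand. The difference of Swit_4895 between the sands turned to 0.22 with slide as a fixed block. The causes were not tested. Signal over background limits the dimmest genes: 5131 of 5306 had a probe well above background on all 15 arrays.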

Other observations

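The tests by blocks of tag numbers and those of the size of differences between precultures were chosen after results had been seen.

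The 18 tested names that stand for several numbered tags included 13 that were higher and 3 that were lower in the DBF-grown than in the salicylate-grown liquid controls, with a median log2 difference of 1.01. As a set they did not stand apart from other genes (camera, adjusted p = 0.619, and adjusted p = 0.977 with an estimated correlation). Probes of such names cannot tell the tags apart.

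Of 54 blocks of 100 tag numbers, camera with a preset correlation of 0.01 called 24 in the DBF-grown response to sand with DBF and 22 between the liquid controls. With an estimated correlation it called 0 in each of the 7 comparisons, and at most 1 block had an unadjusted p under 0.05. The smallest adjusted p with an estimated correlation was 0.769.

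It was asked whether differences between precultures became smaller in sand with DBF. The slope of the differences in sand on those in the liquid controls was 0.53, against 0.96 for simulated arrays with equal true differences and the measured spread between arrays, and 0.512 with both differences taken within a slide. Measurement error alone is thus argued against as the source of the low slope. Slide cannot be judged from the slope within slides. There the controls came from slide 1 and the sand arrays from slide 2, so that slide and environment coincide. The reverse slope was 0.67, also under 1, and the sizes were mixed: the median absolute difference from the median of all genes was 0.62 in sand and 0.63 in the controls, 621 genes were at least 2-fold above and 809 at least 2-fold below that median in sand, against 661 and 833, and the SD of the differences was 0.922 against 1.04 (0.854 against 1.03 with quantile normalization, 0.768 against 0.772 with normexp). Whether the differences became smaller stays open.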
